A study of Mus musculus with 18 samples.

How the data were processed

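RNA was sequenced from hearts of C57 mice, either wild type or with the Kcp gene knocked out, after a sham operation or transverse aortic constriction (TAC), a banding of the aorta that loads the left ventricle with pressure. Per the labels, total RNA was extracted with a Qiagen RNeasy kit and 1.3 ug of it went into each SMARTER mRNA-seq preparation. The time between surgery and tissue collection is not given in the sources used here. There were 18 libraries: 4 wild-type sham, 5 wild-type TAC, 4 knockout sham and 5 knockout TAC.

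The authors provided a single table of 34714 genes by 18 libraries, with 1 column for each library. The unit of the deposited values was inferred as FPKM (fragments scaled by transcript length and by the total of the library), because the label of the table does not name it. The values were never negative, were not whole numbers, summed to between 390453 and 432264 per library, and gave a near constant total in every library once multiplied by transcript length. FPKM and RPKM could not be separated from the values, and neither choice would change a fold change. The submitters' notes give mm10 as the genome build; the aligner and the counter are not given in the sources used here. All gene names matched symbols of the RefSeq annotation of GRCm38 (mm10), from which the coordinates were taken. The sequencing depth of the libraries is unknown, so no counting interval or detection floor is given for any value.

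The design fixed before the data were examined assumed read counts first and named a fallback for FPKM values, and the fallback was used. Values were transformed as log2(FPKM + 1). Genes at 1 FPKM or more in at least 3 libraries were kept, which left 11937 genes. One linear model with a mean for each of the 4 groups was fitted with limma 3.58.1 in R 4.3.3, with intensity trend and robust moderation, and p-values were adjusted by Benjamini-Hochberg at a threshold of 0.05 with no fold threshold. All log2 changes below are differences of log2(FPKM + 1), given with their standard error, and all adjusted p-values of genes are from this limma fit with Benjamini-Hochberg. There were 5 contrasts: TAC against sham in each genotype, knockout against wild type under each surgery, and the genotype by TAC interaction. Knockout sham replicate 2 was left out of the model, because its library name joins those of replicates 3 and 4 of the same group, which leaves 17 libraries. For Kcp, Ccnb1 and Nnt, 2-sided exact permutation tests on log2(FPKM + 1) were computed as well.

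Before the data were examined, 38 gene lists were fixed for the stressed and adult cardiomyocyte, matrix, signalling, the p53 route, the cell cycle, metabolism, stress responses, the cell types a piece of heart can hold, the neighbours of Kcp and sex-linked genes. A list needed 3 tested members, which 35 lists had. Some genes stand in several lists, among them 8 of the 40 matrix genes and 8 of the 17 activated fibroblast markers. Calls of lists that share genes are therefore not independent. The lists were tested with camera from limma at a preset inter-gene correlation of 0.01, and the 175 tests of 35 lists in 5 contrasts were adjusted together by Benjamini-Hochberg. Each camera call is given with the adjusted p obtained with an estimated correlation, and fry from limma was run as an alternative. Members past the threshold were counted over all tested genes and also with p adjusted over the list alone.

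The genes named were chosen by a rule fixed before the data were examined. Kcp came first. A fixed set was always named: Trp53, Cdkn1a, Ccnb1, Mdm2, Nppa, Nppb, Myh6, Myh7, Acta1, Col1a1, Col3a1, Postn, Ccn2, Tgfb1, Tgfb2, Atp2a2, Bmp7, Smad6 and Id1. To these were added, per contrast, up to 8 genes with the largest rise and up to 8 with the largest fall past the threshold, with a mean of at least 1 FPKM and no overlap between the libraries of the groups compared (overlap was not considered for the interaction), leaving out gene models without a proper name and pseudogenes. From each list, up to 4 members with the smallest adjusted p past the threshold were taken, or the 2 with the smallest p where none passed. Genes chosen after their values were seen are identified as such. Some genes that the rule selects are not reported here.

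Alternatives tried were all 18 libraries, a block for the replicate number, a pseudocount of 0.1, no filter on low values, median-ratio scaling, only the 2 groups compared, a log2 fold change of at least 1 as well, and each library left out in turn. A term for the library sets described in the results, and a fit without the 2 TAC libraries that stood apart from their groups, were added after seeing the data. The pipeline was tested on simulated data made from the within-group spread of these libraries on 11937 genes. Because the simulated genes varied independently and held no library sets, the rates it reached need not hold for the real calls. Of genes given a change of 1 on the log2 scale it recovered 100% for TAC in wild type, 93.9% for TAC in knockout, 95.6% for genotype in sham, 100% for genotype after TAC and 82.4% for the interaction; the percentage of false calls was 3.78, 7.37, 5.85, 5.5 and 3.07. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Values per exon or per read were not analysed here, and mitochondrially encoded transcripts, which made up 1 of the fixed lists, were not analysed here either.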

Results

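Heart RNA was measured in 18 libraries from wild-type and Kcp knockout mice after sham surgery or TAC. Of these, 17 entered the model: 4 wild-type sham, 5 wild-type TAC, 3 knockout sham and 5 knockout TAC. Kcp encodes kielin/chordin-like protein, a secreted protein that modulates BMP and TGF-beta signalling. The study asked what its loss does to remodelling of the pressure-overloaded heart, with attention to Trp53, Cdkn1a (p21) and Ccnb1 (cyclin B1). Between 11027 and 11377 genes reached 1 FPKM per library, and the 10 most abundant genes of a library held 15.2% to 17.3% of the summed FPKM. Values are FPKM as mean ± SD over the libraries in the model, and depth is unknown. The labels do not state that each library came from a separate mouse, so the p-values measure the spread between samples whose independence is not stated.

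Kcp (chromosome 6, 29473162 to 29508003) was lower in the knockout libraries but was not absent from them. Its level was 1.03 ± 0.279 FPKM in wild-type sham (n = 4), 1.12 ± 0.204 in wild-type TAC (n = 5), 0.665 ± 0.00891 in knockout sham (n = 3) and 0.762 ± 0.197 in knockout TAC (n = 5). By replicate, wild-type sham had 0.794, 1.43, 0.888 and 1.02 FPKM, and wild-type TAC had 0.985, 1.04, 1.48, 1.07 and 1.04. Knockout sham replicates 1, 3 and 4 had 0.666, 0.673 and 0.655, knockout sham replicate 2, outside the model, had 0.624, and knockout TAC had 0.952, 0.935, 0.791, 0.637 and 0.494. The knockout mean over both surgeries was 67% of the wild-type mean (exact permutation test, 2-sided, p = 0.0014). The difference had p = 0.057 in sham, where the smallest exact p possible is 0.029, and exact p = 0.0079 after TAC, the smallest possible there. In the model the log2 differences were -0.28 ± 0.12 in sham and -0.27 ± 0.10 after TAC, with adjusted p = 0.301 and 0.0843 (limma, Benjamini-Hochberg). TAC did not move Kcp past the threshold in wild type (log2 change 0.07, limma with Benjamini-Hochberg adjusted p = 0.689).

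**Figure D1:**
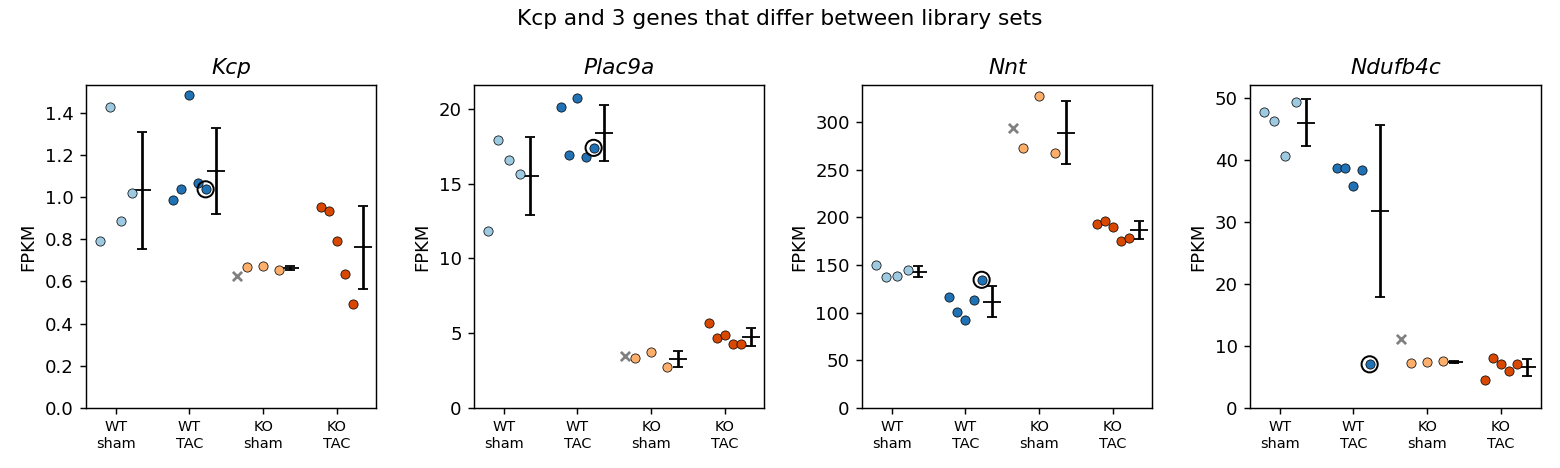
FPKM of Kcp, Plac9a, Nnt and Ndufb4c in each library by group, with dots for libraries, a bar for the mean ± SD over libraries in the model, a grey cross for knockout sham replicate 2 and a ring around wild-type TAC replicate 5. Kcp averaged 0.665 FPKM in knockout sham and 1.03 in wild-type sham, and Ndufb4c was at 7.02 FPKM in wild-type TAC replicate 5.

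The libraries also split in a way that the groups do not explain. Of 11952 genes examined, 17 separated the libraries into 2 sets by more than 0.5 on the log2 scale, among them Ndufb4c, Rps27rt and Rps10. The first set held wild-type sham replicates 1 to 4 and wild-type TAC replicates 1 to 4. The second held wild-type TAC replicate 5 and all 9 knockout libraries, and all 17 genes were lower in it. By the same gap 8 genes separated all wild-type from all knockout libraries. Ndufb4c was at 35.9 to 49.4 FPKM in the first set and 4.47 to 11.2 in the second, and Rps10 was at 47 to 66.9 and 24.2 to 31.6. The first set holds wild-type libraries alone and the second holds 1 wild-type library, so inside a set the genotypes can be compared only after TAC, against that 1 library. A fit with the set as a term was possible and rests on wild-type TAC replicate 5. In that fit the log2 difference of Kcp between genotypes was -0.21 ± 0.22 in sham and -0.22 ± 0.17 after TAC. The permutation test of Kcp over both surgeries took no account of the sets, which nearly follow genotype. Surgery was the main axis of the libraries. The first principal component carried 51.4% of the variance, with sham libraries between -25.8 and -18.2 and TAC libraries between 1.2 and 31.2. Wild-type TAC replicate 5 (1.2, against 8.1 to 14.6 in the other wild-type TAC libraries) and knockout TAC replicate 2 (11.4, against 23.6 to 31.2) stood nearest to sham in their groups.

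TAC in wild-type hearts was compared with sham to describe the response to pressure overload. Nppa and Nppb, the natriuretic peptide genes that mark cardiac wall stress, rose 10.2-fold and 6.09-fold on the log2(FPKM + 1) scale. Nppa went from 158.5 ± 76.5 to 1657 ± 731 FPKM and Nppb from 126 ± 24.3 to 801.2 ± 280 (sham n = 4, TAC n = 5). Acta1, the skeletal actin of the fetal heart, rose 22.8-fold (log2 change 4.51 ± 0.59, limma with Benjamini-Hochberg adjusted p = 0.000138). Postn, which encodes the matrix protein periostin made by activated fibroblasts, rose from 9.624 ± 2.18 to 67.93 ± 33.5 FPKM. The collagen genes Col1a1 and Col3a1 rose by log2 1.42 ± 0.23 and 1.53 ± 0.24. Myh6, the adult myosin heavy chain, and Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell (log2 change -0.19 ± 0.05 and -0.36 ± 0.08). Myh7 had a log2 change of 0.80 ± 0.36 that did not pass (limma with Benjamini-Hochberg adjusted p = 0.127).

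Gene groups moved with these markers in wild type. Of 38 extracellular matrix genes 32 rose and 0 fell (35 and 0 adjusted over the list alone), led by Col4a1 (1.15 ± 0.07), Sparc (0.98 ± 0.09) and Loxl2 (1.20 ± 0.13). For the matrix list camera gave adjusted p = 2.2e-23, and adjusted p = 0.37 with an estimated correlation. Of 15 fetal and stress genes 10 rose and 0 fell (11 and 0 adjusted over the list alone), among them Xirp2 (1.59 ± 0.23). For this list camera gave adjusted p = 6.4e-10, and adjusted p = 0.37 with an estimated correlation. Of 16 activated fibroblast markers 9 rose and 0 fell (10 and 0 adjusted over the list alone), including Meox1 and Mfap4. Camera called these markers (adjusted p = 4.5e-07), with adjusted p = 0.43 with an estimated correlation. Of 16 heat shock genes 14 rose and 0 fell (14 and 0 adjusted over the list alone), with Hspb1 at 1.39 ± 0.17 and Hsp90aa1 at 1.43 ± 0.18. Camera called the heat shock list too (adjusted p = 1.9e-12; adjusted p = 0.37 with an estimated correlation). The near-identical pair Hspa1a and Hspa1b rose by 2.92 ± 0.42 and 2.93 ± 0.44, and their separate values are uncertain.

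Mitochondrial genes went the other way in wild type. Of 27 fatty acid oxidation genes 17 fell and 1 rose (21 and 1 adjusted over the list alone), with Ech1 at -0.75 ± 0.09 and Hadha at -0.46 ± 0.07. Of 43 oxidative phosphorylation genes 31 fell and 0 rose (35 and 0 adjusted over the list alone), with Sdha at -0.44 ± 0.06. Camera gave these lists adjusted p = 1.1e-08 and 3.4e-14 (adjusted p = 0.45 and 0.45 with an estimated correlation). TGF-beta signalling rose in 10 of 21 genes and fell in 3 (11 and 3 adjusted over the list alone). Its members Pmepa1 (0.90 ± 0.10), Tgfb3 (0.67 ± 0.12) and Tgfb1 (0.30 ± 0.08) rose, and camera called the list (adjusted p = 0.012; adjusted p = 0.49 with an estimated correlation). The unfolded protein response rose in 10 of 23 genes, including Atf4 and Creld2, and fell in 1 (13 and 2 adjusted over the list alone). Camera called it as well (adjusted p = 0.00014; adjusted p = 0.45 with an estimated correlation).

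The p53 route in wild type moved in part. Cdkn1a, the cell-cycle inhibitor p21, rose from 9.171 ± 2.83 to 32.23 ± 15.5 FPKM (log2 change 1.65 ± 0.39, limma with Benjamini-Hochberg adjusted p = 0.00719). Trp53 had 10.37 ± 0.566 FPKM in sham and 11.91 ± 1.26 after TAC (adjusted p = 0.174 by limma with Benjamini-Hochberg), and its regulator Mdm2 had a log2 change of 0.04. Of 23 p53 targets 4 rose and 0 fell (4 and 0 adjusted over the list alone), with Phlda3 at 0.72 ± 0.12, and camera did not call the list (adjusted p = 0.053). Ccnb1 was too low for the model, at 0.108 ± 0.0824 FPKM in sham and 0.245 ± 0.126 after TAC (exact permutation p = 0.13). Other large rises were in Cilp, a matrix protein gene (3.17 ± 0.34), and Thbs4 (2.28 ± 0.47). Large falls by the rule for named genes were in Retnla (-1.64 ± 0.17) and Ces1d (-1.51 ± 0.30). Ccl11, an eosinophil chemokine gene, and Pfkfb1 fell by 1.42 and 1.30 on the log2 scale.

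Across the genome 2615 of 11937 genes passed in wild type (21.9%), 1275 higher and 1340 lower after TAC (limma with Benjamini-Hochberg). Without wild-type TAC replicate 5, which leaves the wild-type libraries of the first set, 2627 genes passed. In that library the fetal and stress genes (mean 6.4 on the log2 scale, against 6.87 to 7.26 in the other wild-type TAC libraries), the matrix genes (3.29 against 3.58 to 4.07) and the activated fibroblast markers (2.35 against 2.94 to 3.5) were lowest of the group.

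**Figure D2:**
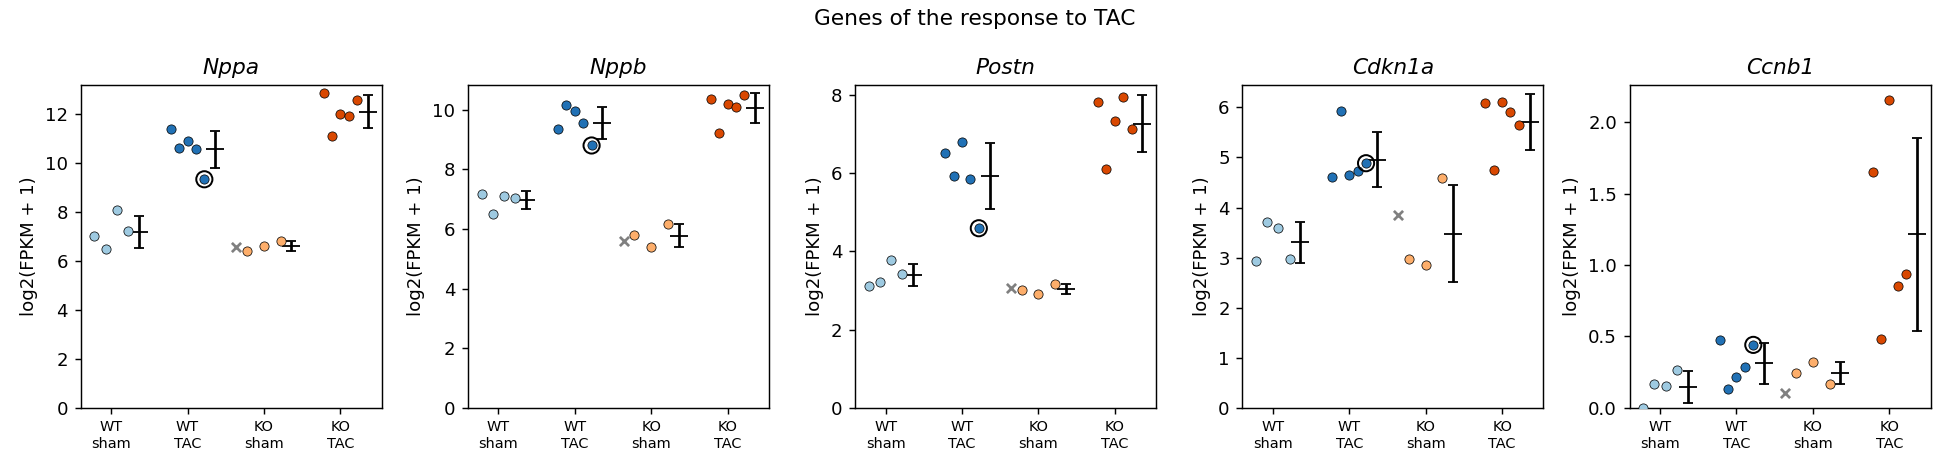
log2(FPKM + 1) of Nppa, Nppb, Postn, Cdkn1a and Ccnb1 in each library by group, with dots for libraries, a bar for the mean ± SD over libraries in the model, a grey cross for knockout sham replicate 2 and a ring around wild-type TAC replicate 5. Nppa averaged 1657 FPKM in wild-type TAC and 4770 in knockout TAC, and Ccnb1 was at 0.396 to 3.45 FPKM in knockout TAC.

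TAC in Kcp knockout hearts was compared with knockout sham to describe the same response in the mice labelled knockout, whose Kcp RNA was lower but not absent. Nppa rose from 96.9 ± 14.4 to 4770 ± 2060 FPKM and Nppb from 55.26 ± 14.6 to 1124 ± 325 (sham n = 3, TAC n = 5). These were rises of 45.1-fold and 19.6-fold on the log2(FPKM + 1) scale. Postn rose 18.9-fold (log2 change 4.24 ± 0.44, limma with Benjamini-Hochberg adjusted p = 4.55e-06) and Acta1 29.8-fold. The log2 change of Acta1 was 4.90, and 3.97 without knockout sham replicate 3 and 5.77 without knockout sham replicate 4. Ccn2, a matricellular gene induced by TGF-beta, rose from 22.82 ± 5.04 to 258 ± 118 FPKM. Myh7 rose (1.73 ± 0.39), and Myh6 (-0.50 ± 0.06), Atp2a2 (-0.76 ± 0.09), the troponin gene Tnni3 (-0.84 ± 0.07) and the phospholamban gene Pln (-0.77 ± 0.08) fell. Gdf15, a secreted stress cytokine gene, rose from 0.7143 ± 0.235 to 10.81 ± 4.26 FPKM, and Sprr1a, listed at 0 in knockout sham, passed the threshold after TAC. The largest falls by the rule for named genes included Ces1d (-2.92 ± 0.32), Retnla (-2.60 ± 0.18), Pfkfb1 (-2.47 ± 0.18) and Sbk2, a striated muscle kinase gene (-2.23 ± 0.17).

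In the knockout, 37 of 38 matrix genes rose and 0 fell (38 and 0 adjusted over the list alone), with Bgn at 2.32 ± 0.19, Sparc at 1.48 ± 0.10 and Col4a1 at 1.29 ± 0.07. For the matrix list camera gave adjusted p = 6e-22, and adjusted p = 0.37 with an estimated correlation. Of the 15 fetal and stress genes 13 rose, among them Ankrd1 (2.92 ± 0.28), and 0 fell (13 and 1 adjusted over the list alone). Camera called them (adjusted p = 9.3e-08; adjusted p = 0.37 with an estimated correlation). Fatty acid oxidation fell in 25 of 27 genes and rose in 1 (26 and 1 adjusted over the list alone), with Acaa2 at -1.43 ± 0.13 and Ech1 at -1.27 ± 0.10. Oxidative phosphorylation fell in 42 of 43 and rose in 0 (42 and 0 adjusted over the list alone), with Cox7a1 at -1.03 ± 0.10 and Ndufs1 at -0.64 ± 0.06. Camera gave these 2 lists adjusted p = 1.3e-17 and 1e-22 (adjusted p = 0.37 and 0.37 with an estimated correlation).

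Activated fibroblast markers rose in 12 of 16 genes in knockout (14 higher and 1 lower adjusted over the list alone). Camera called these markers (adjusted p = 2.9e-07), with adjusted p = 0.42 with an estimated correlation. TGF-beta signalling rose in 14 of 21 genes and fell in 2 (14 and 2 adjusted over the list alone), with Tgfb2 at 1.68 ± 0.25 and Tgfbr1 at 0.85 ± 0.11. It was called by camera (adjusted p = 0.0011; adjusted p = 0.41 with an estimated correlation). Macrophage markers rose in 12 of 21 genes (13 adjusted over the list alone), including Cd14, Tyrobp and Adgre1. These too were called (camera adjusted p = 0.0011; adjusted p = 0.51 with an estimated correlation). Immediate early genes rose in 9 of 24 (12 adjusted over the list alone), including Atf3 and Myc (camera adjusted p = 0.00016; adjusted p = 0.50 with an estimated correlation). Heat shock genes rose in 6 of 16 and fell in 1 (7 and 2 adjusted over the list alone) and were not called (camera adjusted p = 0.066).

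Proliferation and p53 genes were part of the knockout response. Of 16 G2/M genes 14 rose and 1 fell (14 and 1 adjusted over the list alone). The G2/M and G1/S lists have 32 members each, of which 16 and 25 met the filter on low values. Knockout TAC libraries alone can meet that filter, so the tested members may favour genes that are high there. The ubiquitin-conjugating enzyme gene Ube2c rose by 2.19 ± 0.39, Cdkn3 by 0.99 ± 0.19 and the spindle gene Tpx2 by 0.88 ± 0.17. Of 25 G1/S genes 11 rose and 0 fell (11 and 0 adjusted over the list alone), including Ccnd2, Mcm6 and E2f1. Camera gave the cell-cycle lists adjusted p = 0.00052 and 0.003 (adjusted p = 0.53 and 0.63 with an estimated correlation). Ccnb1 was at 0.184 ± 0.0622 FPKM in sham and 1.54 ± 1.25 after TAC (exact permutation p = 0.054, where 0.018 is the smallest possible). Cdkn1a rose from 12.04 ± 9.54 to 53.83 ± 17.2 FPKM (log2 change 2.23 ± 0.42, limma with Benjamini-Hochberg adjusted p = 0.000718). Knockout sham replicates 1, 3 and 4 had 6.834, 6.24 and 23.05 FPKM of Cdkn1a, and without replicate 4 its change was 2.79. Trp53 did not pass (0.23 ± 0.10, limma with Benjamini-Hochberg adjusted p = 0.0796), though it did without knockout sham replicate 3 (0.38, adjusted p = 0.00501 by limma with Benjamini-Hochberg).

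Of 23 p53 targets 11 rose and 1 fell in knockout (12 and 1 adjusted over the list alone), including Phlda3 (1.05 ± 0.13), Perp and Zmat3. Camera called the p53 list (adjusted p = 0.036; adjusted p = 0.37 with an estimated correlation). It was not called without knockout sham replicate 1, knockout sham replicate 3 or knockout TAC replicate 5 (camera adjusted p = 0.055, 0.09 and 0.053). Apoptosis regulators rose in 11 of 22 genes and fell in 1 (11 and 1 adjusted over the list alone). Bak1 and Casp8, which promote cell death, rose, and so did Bcl2, which restrains it. For the apoptosis list camera gave adjusted p = 0.013, and adjusted p = 0.37 with an estimated correlation.

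A total of 4633 of 11937 genes passed in the knockout (38.8%), 2515 higher and 2118 lower (limma with Benjamini-Hochberg). All knockout libraries belong to the second set. Knockout TAC replicate 2 had the lowest mean of its group for fetal and stress genes (6.81, against 7.45 to 7.65), matrix genes (3.82, against 4.11 to 4.7) and activated fibroblast markers (3.05, against 3.54 to 4.23).

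The TAC responses of the genotypes were then set side by side. Across the 11937 genes, which are not independent replicates, the log2 changes in wild type and knockout correlated with r = 0.79 (Spearman rho = 0.71). Both called 1018 genes higher, where 269 would be shared by chance, and 975 lower, where 238 would be, and 5 genes went in opposite directions. Of the 2615 genes called in wild type, 1634 (62.5%) had the larger change in knockout, and the median ratio of the knockout change to the wild-type change was 1.22. Over the 4633 genes called in knockout, a choice that favours large knockout changes, the ratio was 1.75 and 92.2% had the larger change in knockout. The difference between the responses was tested gene by gene as the interaction. It passed for 111 genes, 45 with the larger and 66 with the smaller value in the knockout response (limma with Benjamini-Hochberg, 2245 genes at unadjusted p under 0.05).

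The interaction genes included Edn3, which encodes the vasoactive peptide endothelin-3. It went from 0.4847 ± 0.16 to 2.549 ± 0.241 FPKM in wild type and from 0.4734 ± 0.381 to 8.708 ± 3.04 in knockout (interaction 1.43 ± 0.29, limma with Benjamini-Hochberg adjusted p = 0.034). Uchl1, a deubiquitinase gene, rose in both genotypes and more in knockout (1.27 ± 0.25). Cpxm2 (1.13 ± 0.16), Adam19 (0.99 ± 0.19) and Cd44, a hyaluronan receptor gene (0.91 ± 0.20), had higher values in the knockout response too. The kinase genes Sbk2 (-1.33 ± 0.23) and Sbk3 (-1.30 ± 0.21), Pfkfb1 (-1.17 ± 0.24) and the acyl-CoA thioesterase gene Acot1 (-1.08 ± 0.19) had lower values in the knockout response. In sham, Cpxm2 was lower and Pfkfb1 higher in knockout, opposite in sign to their interactions. At these genes the interaction holds that sham difference and need not mean that the genotypes differed after TAC. Of 27 fatty acid oxidation genes 4 passed, all lower (23 lower adjusted over the list alone), namely Acsl1 (-0.56 ± 0.10), Slc25a20, Eci1 and Etfdh. Of 43 oxidative phosphorylation genes 0 passed (31 lower adjusted over the list alone). Camera called both lists lower (adjusted p = 8.6e-20 and 7.5e-19, and adjusted p = 0.37 and 0.38 with an estimated correlation). These interactions also hold a sham difference of opposite sign. The fatty acid oxidation median between genotypes was 0.22 in sham and -0.13 after TAC, with -0.37 for the interaction. For oxidative phosphorylation these medians were 0.14, -0.12 and -0.25. Of 16 heat shock genes 1 passed, lower (1 higher and 8 lower adjusted over the list alone), and of 38 matrix genes 0 passed (7 higher adjusted over the list alone). Camera called the heat shock list lower and the matrix list higher (adjusted p = 8.9e-07 and 2.8e-09; adjusted p = 0.37 and 0.50 with an estimated correlation).

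The main TAC markers did not pass the interaction test. It was 2.14 ± 0.61 for Nppa, 1.69 ± 0.43 for Nppb, 1.69 ± 0.60 for Postn and 0.58 ± 0.57 for Cdkn1a, with adjusted p = 0.0903, 0.0695, 0.149 and 0.627 (limma, Benjamini-Hochberg). Trp53 had 0.05 (limma with Benjamini-Hochberg adjusted p = 0.88). Of the 23 p53 targets 0 passed, and 0 adjusted over the list alone (camera adjusted p = 0.31). Without knockout TAC replicate 2, Nppa (2.39), Nppb (1.90) and Postn (1.98) passed, with adjusted p = 0.0312, 0.0131 and 0.0491 by limma with Benjamini-Hochberg. Nppb had a lower mean in knockout sham than in wild-type sham, and after TAC its genotype difference did not pass. Its interaction thus holds that sham difference and need not mean a higher level in knockout after TAC.

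With the set of libraries as a term the interaction count was 17 (4 higher, 13 lower). In this contrast the term only takes wild-type TAC replicate 5 out of the estimate, so the count equals that without the library (17, 4 higher and 13 lower) and is no test of the sets. Cpxm2 (1.20 ± 0.15), Akip1 (0.85 ± 0.14), Sbk2 (-1.46 ± 0.19), Sbk3 (-1.32 ± 0.22), Acot1 (-1.05 ± 0.20), Whrn and Klhl33 still passed. Edn3 (1.42 ± 0.30), Uchl1 (1.23 ± 0.26), Adam19 (0.98 ± 0.20), Cd44 (0.83 ± 0.19) and Pfkfb1 (-1.09 ± 0.24) did not, with adjusted p = 0.0573, 0.0573, 0.0539, 0.0629 and 0.0573 by limma with Benjamini-Hochberg. The fatty acid oxidation genes Acsl1, Slc25a20, Eci1 and Etfdh did not either (limma with Benjamini-Hochberg adjusted p = 0.052, 0.0573, 0.0631 and 0.0765). Their values were nearly the same with the term (-0.54, -0.47, -0.48 and -0.44) as without it (-0.56, -0.47, -0.50 and -0.45). Of the interaction genes named, Cpxm2, Akip1 and Sbk2 passed in all 17 fits that left out 1 library. Edn3, Uchl1, Cd44 and Pfkfb1 did not in 10, 12, 13 and 13 of these fits, nor Acsl1, Slc25a20, Eci1 and Etfdh in 4, 11, 13 and 14. Median-ratio scaling gave 199 genes (53 higher, 146 lower). Leaving out wild-type sham replicates 1 to 4 in turn moved the count of 111 to 23, 36, 10 and 33, and leaving out wild-type TAC replicates 2, 4 and 5 to 43, 34 and 17. It was 7, 43 and 58 without knockout sham replicates 1, 3 and 4, and 33, 597, 40, 30 and 171 without knockout TAC replicates 1 to 5.

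**Figure D3:**
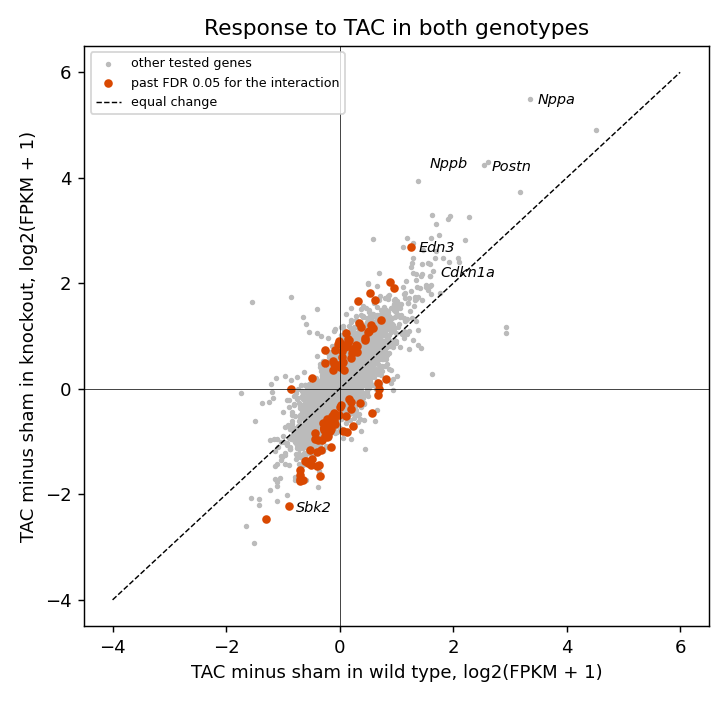
Change after TAC in log2(FPKM + 1) for each of 11937 genes, wild type on the x axis and knockout on the y axis; the dashed line marks equal change and the 111 genes that passed the interaction test are in orange. The changes correlated across genes with r = 0.79.

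Knockout and wild-type hearts were compared after sham surgery to describe how the genotypes differed without load. Plac9a (chromosome 14, 25888403 to 25902893) had 15.48 ± 2.62 FPKM in wild-type sham (n = 4) and 3.266 ± 0.506 in knockout sham (n = 3). Its log2 difference was -1.94 ± 0.12 (limma with Benjamini-Hochberg adjusted p = 2.67e-08) and that of its near-identical copy Plac9b was -1.73 ± 0.10; which copy the reads came from is uncertain. Cpxm2, a carboxypeptidase-like gene, was lower in knockout (13.77 ± 1.91 and 5.035 ± 0.281 FPKM). Nnt (chromosome 13, 119335527 to 119409257), the mitochondrial transhydrogenase gene, was higher, at 142.7 ± 5.85 FPKM in wild-type sham and 289.2 ± 33.2 in knockout sham. All 9 knockout libraries lay above every wild-type library at Nnt. With the 8 knockout libraries of the model the exact permutation p over both surgeries was 4.1e-05, the smallest possible. The rule that named Nnt asks for no overlap between the sham groups, so this p is no independent test. Genotype also nearly follows the library sets. Rab4a, a gene of endosome recycling (3.132 ± 0.924 and 10.56 ± 1.14 FPKM), and Wdfy1 (2.31 ± 0.322 and 5.29 ± 0.426) were higher in knockout. Dynlt1b was higher as well (1.58 ± 0.12), though near-identical copies make its own level uncertain.

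A few metabolic genes passed as higher in knockout sham, and those named here lost their calls with the set of libraries as a term. That term widens the standard errors and rests on wild-type TAC replicate 5, so the lost calls alone do not show a batch effect. The heart fatty acid binding protein gene Fabp3 had 2876 ± 235 FPKM in wild type and 4022 ± 134 in knockout (0.49 ± 0.09, limma with Benjamini-Hochberg adjusted p = 0.0102). Acot2 (0.53 ± 0.11), Scd4 (1.35 ± 0.25), Pfkfb1 (1.15 ± 0.19) and Gapdh (0.40 ± 0.09) were higher as well. Of 27 fatty acid oxidation genes 2 were higher and 0 lower (18 and 0 adjusted over the list alone), and of 43 oxidative phosphorylation genes 0 passed (1 higher adjusted over the list alone). Camera called both lists higher (adjusted p = 1.2e-15 and 1.6e-10; adjusted p = 0.37 and 0.49 with an estimated correlation).

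Of 24 immediate early genes, which respond within minutes to stimulation, 0 passed in sham (0 higher and 8 lower adjusted over the list alone), with a median of -0.81. Camera called them lower in knockout (adjusted p = 1.6e-08; adjusted p = 0.41 with an estimated correlation). Their mean was 4.55, 4.07, 4.57 and 3.23 on the log2 scale in wild-type sham replicates 1 to 4 and 3.13 to 3.33 in the knockout sham libraries. Fosb had 16.2, 4.6, 27 and 0.793 FPKM in the wild-type sham libraries and a log2 difference of -2.45 ± 0.69 (limma with Benjamini-Hochberg adjusted p = 0.11). It passed without wild-type sham replicate 4 (-3.18, adjusted p = 0.00757 by limma with Benjamini-Hochberg).

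The retrocopy genes Ndufb4c (-2.49 ± 0.43), Rps27rt (-2.18 ± 0.41), Rpl37rt, Ndufb4b and Rps23rg1 were lower in knockout sham. At these genes wild-type TAC replicate 5 lay within the range of the knockout libraries, and the source of their reads is uncertain. Ribosomal protein genes were called higher by camera (1 of 36 passed, 4 adjusted over the list alone; adjusted p = 0.0011; adjusted p = 0.57 with an estimated correlation). Camera called mural cell markers lower with 0 of 15 passed (0 higher and 1 lower adjusted over the list alone; adjusted p = 0.027; adjusted p = 0.51 with an estimated correlation). Brown fat markers were called higher with 0 of 5 passed (3 adjusted over the list alone; camera adjusted p = 0.034; adjusted p = 0.37 with an estimated correlation). Macrophage markers were called lower with 0 of 21 passed (0 adjusted over the list alone; camera adjusted p = 0.025; adjusted p = 0.64 with an estimated correlation). Their median was -0.18, and 0.07 with the set of libraries as a term. Leaving out 1 library ended the call for mural cell markers (wild-type sham replicate 4, knockout sham replicates 1 and 4), macrophage markers (wild-type sham replicates 3 and 4, knockout sham replicate 3) and brown fat markers (knockout sham replicates 1 and 4). Matrix genes and p53 targets were not called (0 of 38 and 0 of 23 passed; camera adjusted p = 0.47 and 0.48). Cdkn1a had a log2 difference of 0.17, or -0.39 without knockout sham replicate 4. Trp53 had -0.03, and Ccnb1 had exact permutation p = 0.26.

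In all, 151 of 11937 genes passed in sham (1.26%), 77 higher and 74 lower (limma with Benjamini-Hochberg). With the set of libraries as a term the count was 12 (4 higher, 8 lower), and Plac9a (-1.85 ± 0.22), Plac9b, Cpxm2 (-1.62 ± 0.20), Dynlt1b (1.66 ± 0.22) and Wdfy1 (1.21 ± 0.19) still passed. Rab4a (1.46 ± 0.29), Nnt (0.66 ± 0.15) and Fabp3 (0.36 ± 0.16) did not, with adjusted p = 0.1, 0.182 and 0.803 by limma with Benjamini-Hochberg. Scd4 (0.81 ± 0.42), Pfkfb1 (0.73 ± 0.31), Acot2 (0.27 ± 0.18) and Gapdh (0.01 ± 0.12) did not either (limma with Benjamini-Hochberg adjusted p = 0.87, 0.796, 0.915 and 0.994). The term widened the standard errors and carried the weak TAC response of wild-type TAC replicate 5 into these sham values. Calls lost with it are by themselves no evidence of a batch effect. Of 7 fits that left out 1 library, Acot2 did not pass in 4, Gapdh in 6 and Scd4 in 1. The count of 151 was 86 and 78 without wild-type sham replicates 1 and 3, and 93, 50 and 73 without knockout sham replicates 1, 3 and 4.

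Knockout and wild-type hearts after TAC were compared to ask how the genotypes differed under load. Nppa was 2.91-fold higher in knockout (log2 difference 1.54 ± 0.39, n = 5 and 5). Col1a1 (chromosome 11, 94936224 to 94953042) had 21.53 ± 7.71 FPKM in wild type and 42.46 ± 14.5 in knockout, a 1.94-fold difference, and Col3a1 was 1.92-fold higher. The elastin gene Eln (10.45 ± 2.01 and 24.87 ± 7.65 FPKM), the proteoglycan gene Bgn (250.3 ± 59.3 and 469.8 ± 98.4) and Gdf15 (2.831 ± 0.893 and 10.81 ± 4.26) were higher in knockout. Myh6 was lower (4733 ± 368 and 4037 ± 168 FPKM). The chaperone genes Hspa1a (58.75 ± 30.6 and 11.94 ± 5.82 FPKM), Hspa1b, Hsph1 (-1.20 ± 0.23) and Dnaja1 (-1.06 ± 0.18) were lower in knockout, as was the lipid hydrolase gene Ces1d (27.43 ± 6.18 and 8.193 ± 5.21 FPKM). Nppb (0.50 ± 0.27), Myh7 (0.55) and Acta1 (-0.16) did not pass, with adjusted p = 0.264, 0.33 and 0.898 by limma with Benjamini-Hochberg. Nppa (1.35, adjusted p = 0.0639) and Col3a1 (0.87, adjusted p = 0.0521) did not pass without knockout TAC replicate 1 (limma, Benjamini-Hochberg).

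Matrix genes and activated fibroblast markers were higher in knockout after TAC. Of 38 matrix genes 24 were higher and 0 lower (31 and 0 adjusted over the list alone), including Sparc (0.58 ± 0.09) and Col4a1 (0.41 ± 0.06). For the matrix list camera gave adjusted p = 1.7e-15, and adjusted p = 0.41 with an estimated correlation. Of 16 activated fibroblast markers 6 were higher (8 higher and 1 lower adjusted over the list alone), including Sfrp1, Ccn5 and Mfap4. Camera called these markers (adjusted p = 0.00034), with adjusted p = 0.50 with an estimated correlation. The list of general fibroblast markers was not called (2 of 16 higher and 2 lower, 3 and 2 adjusted over the list alone; camera adjusted p = 0.91), with a median of 0.01, or -0.01 after median-ratio scaling. Among fetal and stress genes 5 of 15 were higher (5 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.015; adjusted p = 0.51 with an estimated correlation). That call was not made without wild-type TAC replicate 1 or wild-type TAC replicate 5 (camera adjusted p = 0.055 and 0.07).

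Of 16 heat shock genes 8 were lower and 1 higher after TAC (12 and 1 adjusted over the list alone; camera adjusted p = 3.3e-07; adjusted p = 0.37 with an estimated correlation). The list mean was 6.76 to 6.89 on the log2 scale in knockout TAC and 7.18 to 7.7 in wild-type TAC. Fatty acid oxidation was lower in 8 of 27 genes and higher in 1 (11 and 1 adjusted over the list alone), with Ppara, the nuclear receptor that drives the pathway, at -0.38 ± 0.07. Oxidative phosphorylation was lower in 9 of 43 and higher in 0 (15 and 0 adjusted over the list alone). Camera gave the mitochondrial lists adjusted p = 3.5e-06 and 2.3e-08 (adjusted p = 0.50 and 0.50 with an estimated correlation). Glycolysis genes split, with 8 of 22 higher, including Gapdh (0.58 ± 0.07), Eno1 and Pgk1, and 3 lower, including the glucose transporter gene Slc2a4 (11 and 5 adjusted over the list alone). Camera called the glycolysis list higher (adjusted p = 0.048; adjusted p = 0.50 with an estimated correlation), but not without wild-type TAC replicate 1, 3 or 4 or knockout TAC replicate 3 or 5. The unfolded protein response was lower in 7 of 23 genes, with Hspa5 at -0.26 ± 0.05, and higher in 1 (9 and 2 adjusted over the list alone). For it camera gave adjusted p = 0.00073, and adjusted p = 0.46 with an estimated correlation. Apoptosis regulators were higher in 4 of 22 (8 adjusted over the list alone; camera adjusted p = 0.005; adjusted p = 0.37 with an estimated correlation), with both Bak1 (0.42 ± 0.05) and Bcl2 (0.58 ± 0.12).

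Tested cell-cycle genes were higher in knockout after TAC. Only 16 of 32 G2/M and 25 of 32 G1/S members met the filter on low values. Because knockout TAC libraries alone can meet it, the counts below may favour a higher level in knockout. Of 16 G2/M genes 8 passed, all higher (14 adjusted over the list alone), among them Ube2c (2.592 ± 0.804 and 11.35 ± 8.4 FPKM), Ccnb2 (0.88 ± 0.18) and Tpx2. Of 25 G1/S genes 9 were higher and 0 lower (17 and 0 adjusted over the list alone), including Ccnd2 (0.56 ± 0.11). Camera gave the cell-cycle lists adjusted p = 1e-07 and 7.7e-07 (adjusted p = 0.45 and 0.49 with an estimated correlation). Ccnb1 was at 0.0943 to 0.391 FPKM in wild-type TAC and 0.396 to 3.45 in knockout TAC. At Ccnb1 5 of 5 knockout libraries lay above all wild-type libraries (exact permutation p = 0.0079, the smallest possible). The G2/M mean by replicate was 2.01, 1.34, 2.39, 1.23 and 1.36 on the log2 scale in knockout TAC and 0.66 to 1.15 in wild-type TAC. Cdkn1a had 0.74 ± 0.36, Trp53 0.01 ± 0.09 and Mdm2 -0.06, with adjusted p = 0.21, 0.942 and 0.498 (limma, Benjamini-Hochberg). Of 23 p53 targets 1 was higher, Phlda3 (0.52 ± 0.11), and 0 lower (3 and 1 adjusted over the list alone; camera adjusted p = 0.6).

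TGF-beta signalling was higher in 7 of 21 genes (8 adjusted over the list alone), including Ltbp3 (0.50 ± 0.11) and Tgfbr1 (0.43 ± 0.10). Camera called it (adjusted p = 0.034; adjusted p = 0.50 with an estimated correlation), but not without wild-type TAC replicate 1 or 2 or knockout TAC replicate 1 (adjusted p = 0.057, 0.092 and 0.085). Tgfb1 had 0.10 (limma with Benjamini-Hochberg adjusted p = 0.395). The list for BMP signalling, which Kcp modulates, holds Kcp itself as a tested member. It had 3 of 17 genes higher and 0 lower (5 and 1 adjusted over the list alone). Camera did not call it (adjusted p = 0.22). Its members Bmp6 (0.49 ± 0.08) and Smad6, an inhibitor of BMP signalling (0.35 ± 0.10), were higher, Smad6 not without wild-type TAC replicate 2 or 4 or knockout TAC replicate 1. Bmp7 was under the filter, at 0.5221 ± 0.16 FPKM in wild-type TAC and 0.3302 ± 0.107 in knockout TAC. Adult cardiomyocyte genes were lower in 5 of 23 and higher in 1 (9 and 2 adjusted over the list alone; camera adjusted p = 0.0072; adjusted p = 0.45 with an estimated correlation). Postn (67.93 ± 33.5 and 168 ± 71.8 FPKM, adjusted p = 0.0383) and Atp2a2 (-0.23 ± 0.07, adjusted p = 0.0493) passed with all libraries (limma, Benjamini-Hochberg). They did not in 7 of 10 fits that left out 1 library, with adjusted p up to 0.101 and 0.139 by limma with Benjamini-Hochberg. For both, the call held without wild-type TAC replicate 1, wild-type TAC replicate 3 or knockout TAC replicate 2. Ccn2 (1.04 ± 0.31, limma with Benjamini-Hochberg adjusted p = 0.0409) passed without knockout TAC replicate 2 and in none of the other 9 such fits.

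After TAC 1350 of 11937 genes passed (11.3%), 779 higher and 571 lower in knockout (limma with Benjamini-Hochberg), or 632 and 728 after median-ratio scaling. With the set of libraries as a term 243 passed (153 higher, 90 lower). That fit sets the knockout TAC libraries against wild-type TAC replicate 5 alone, whose response was weak (Nppa 646 FPKM, against 1510 to 2670 in the other wild-type TAC libraries, and Postn 23.1 against 56.5 to 110). Its values for TAC markers carry that weak response and are no separate evidence for a genotype difference. The 243 included Nppa (2.76 ± 0.57), Postn (2.68 ± 0.52), Col1a1 (1.57 ± 0.33), Col3a1 (1.64 ± 0.33), Eln, Bgn, Myh6 (-0.37 ± 0.08), Atp2a2 (-0.53 ± 0.10), Ces1d, Phlda3, Bak1 and Bcl2. Gdf15 (1.76 ± 0.44), Hspa1a (-1.89 ± 0.72), Hsph1 (-0.89 ± 0.41) and Dnaja1 (-0.97 ± 0.33) did not pass in that fit (limma with Benjamini-Hochberg adjusted p = 0.0527, 0.202, 0.295 and 0.145). Neither did Ube2c (1.55 ± 0.61), Ccnb2 (0.98 ± 0.32), Ccnd2 (0.26 ± 0.17) and Gapdh (0.27 ± 0.10), with adjusted p = 0.213, 0.128, 0.5 and 0.145 (limma, Benjamini-Hochberg). Calls were lost as well for Hspa1b, Tpx2, Eno1, Pgk1, Hspa5 and Ltbp3 (limma with Benjamini-Hochberg adjusted p = 0.199, 0.246, 0.0664, 0.285, 0.0752 and 0.141). Their values with the term were -1.94 ± 0.73, 0.62 ± 0.26, 0.46 ± 0.12, 0.19 ± 0.09, -0.32 ± 0.09 and 0.57 ± 0.19, against -2.34 ± 0.41, 0.63 ± 0.15, 0.45 ± 0.07, 0.29 ± 0.05, -0.26 ± 0.05 and 0.50 ± 0.11 without it. The standard errors grew, because the wild-type side is 1 library. Ccn2 (1.35 ± 0.54), Smad6 (0.24 ± 0.17), Bmp6 (0.37 ± 0.14) and Tgfbr1 (0.57 ± 0.17) had adjusted p = 0.227, 0.527, 0.203 and 0.0903 (limma, Benjamini-Hochberg). The set term left 15 of 38 matrix genes and 6 of 16 activated fibroblast markers higher (camera adjusted p = 4e-23 and 1.8e-10; adjusted p = 0.30 and 0.30 with an estimated correlation), lists whose means were lowest of the group in that library. It left 0 of 16 G2/M, 0 of 25 G1/S and 0 of 16 heat shock genes past the threshold (camera adjusted p = 0.00024, 0.0014 and 0.01; adjusted p = 0.49, 0.56 and 0.49 with an estimated correlation). The count of 1350 fell to 870 without wild-type TAC replicate 4 and to 663 and 857 without knockout TAC replicates 1 and 4.

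**Figure D4:**
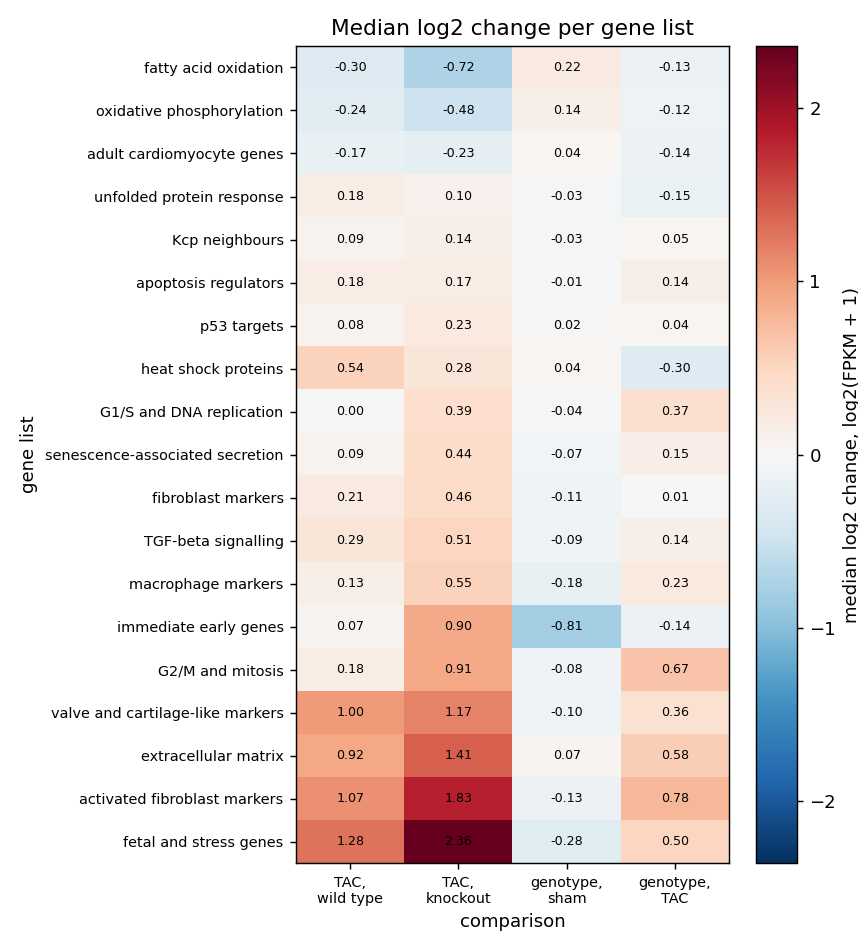
Median log2 change of the tested members of 19 gene lists (y axis) in 4 comparisons (x axis), with colour for the median. The matrix list has a median of 0.92 for TAC in wild type, 1.41 for TAC in knockout and 0.58 for genotype after TAC.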

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

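The tests of the library sets, the mouse substrain, duplicated segments, the size of the TAC response and the Kcp RNA in this part were chosen only after the result was seen; the comparison with other splits of the samples was planned. Of 66 sets of libraries searched for a library far from the others of its group, 2 held one, where 3.3 would be found by chance, which singles out about 1 in 20 groups.

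Those 2 were Kcp in wild-type TAC replicate 3 (1.48 FPKM, the others 0.985 to 1.07) and Cdkn1a in wild-type TAC replicate 2 (59.7 FPKM, the others 23.3 to 28.5).

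The response to TAC differed between genotypes at 111 genes by the interaction test. Of the named ones, the knockout response was higher for Edn3 (log2 1.43 ± 0.29), Uchl1 (1.27 ± 0.25), Cpxm2 (1.13 ± 0.16), Adam19 (0.99 ± 0.19), Nlrc3 (0.94 ± 0.21), Cd44 (0.91 ± 0.20), Aldh1a1 (0.87 ± 0.19) and Akip1 (0.87 ± 0.13). It was lower for Sbk2 (-1.33 ± 0.23), Sbk3 (-1.30 ± 0.21), Pfkfb1 (-1.17 ± 0.24), Acot1 (-1.08 ± 0.19), Whrn (-1.06 ± 0.19), Stard10 (-1.05 ± 0.20), Nle1 (-1.04 ± 0.22) and Klhl33 (-1.03 ± 0.18). For Cpxm2 and Pfkfb1 the genotypes already differed in sham in the opposite direction, so their interactions hold that sham difference. Of 100 splits of the libraries 2 gave as many genes, the real one included, and the highest other gave 260, above the real 111. That split kept the genotype of all 10 TAC libraries and of 1 of 7 sham libraries, so it adds the genotype differences of both surgeries together.

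A first pattern was the difference between genotypes in sham, where 169 genes passed without wild-type TAC replicate 5 and 64 of them differed in the same direction by at least 0.3 after TAC. At 33 of the 64 genes wild-type TAC replicate 5 lay more than halfway to the knockout libraries, but 17 of these were chosen for that. Of the 47 others 16 lay so (34%, against 0% to 10.5% for the other wild-type TAC libraries, each with genes chosen without it), which is consistent with a difference between sequencing or library batches; 5 of the 16 also passed for TAC in wild type. At the other 31 it lay on the wild-type side, which is how these genes were set apart, so its place there is no test of such a difference. This also rests on 1 library, and there batch and genotype cannot be told apart. For these 31 genes a different substrain or donor stays open. Nnt, which carries a deletion in C57BL/6J mice and not in C57BL/6N mice, was higher in all 9 knockout libraries than in every wild-type library, but it is itself 1 of the 31 and was chosen for such a difference. Of the 31 genes, 11 had another of them within 1 Mb (mean 1.6 and highest 10 in 10000 random sets, permutation p = 1e-04, the smallest they can give). Among the 11 are near-identical copies that can share reads, such as Plac9a with Plac9b and Dynlt1b with Dynlt1c. The same difference may thus be counted several times, so the p overstates the clustering. It also cannot tell copy number or haplotype of duplicated segments, which may contribute, from another cause at the same loci. Loss of Kcp itself stays open, untested beside these.

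Next came the larger TAC response in knockout, a median ratio of 1.22 over the genes called in wild type. The ratio was 1.21 after median-ratio scaling, but the scaling factors lay between 0.956 and 1.05. Such a shift also moves the ratios of rising and falling genes in opposite senses. The median ratio could therefore hardly change, and this cannot decide whether scaling of the deposited values contributes. Inside the library sets the ratio was above 1 in all 16 fits that left out 1 library (1.08 to 1.25), but each genotype then has its own set, so a batch difference and genotype cannot be told apart. Genotype changes after TAC correlated with TAC changes in wild type across genes at a mean r of 0.34 (0.18 to 0.45 over 20 splits of the wild-type TAC libraries between the estimates), as a stronger constriction in the knockout mice would give; a stronger response to the same constriction would give it too, and the measured pressure load was not used here. That loss of Kcp enlarges the response is a hypothesis these data leave open.

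The last pattern was the presence of Kcp RNA in knockout libraries at 67% of the wild-type mean. Wild-type RNA or reads mixed into them is argued against as the whole source, since Plac9a reached at most 33.3% of its wild-type level in any knockout library. For swapped or mislabelled libraries 3 choices of genes were tried: genes called under the other surgery put 4 libraries out of place, all knockout sham, while those of them not called by TAC put 0 out of place, and with the 31 genes above the outcome was fixed by how they were chosen; 1049 of the 1350 genes called after TAC (77.7%) also responded to TAC, which makes the first choice a poor test, and a swap with an outside sample stays open. Reads from parts of the gene outside the deleted part could give this level, and values per exon were not analysed here.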

How the results depend on the processing

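The term for library sets and the fit without the TAC libraries that stood apart were chosen only after the result was seen. All other alternatives, the lists, the named genes and the threshold were chosen before the data were examined. Another count test, other size factors and a low-count filter were not run, because the values are not counts. Depth is unknown, so what it limits cannot be stated.

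TAC in wild type and TAC in knockout gave counts within 1.5 times of 2615 and 4633 in all alternatives except the fold threshold. Requiring a log2 change of 1 or more left 115 and 428 genes for TAC in wild type and knockout, 24 and 62 for genotype in sham and after TAC, and 14 for the interaction, as a stricter threshold must. With a pseudocount of 0.1 the counts were 2596, 4637, 142, 1310 and 106.

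All 18 libraries gave 227 genes in sham (99 higher, 128 lower) and 300 for the interaction (173 higher, 127 lower). Comparing only the 2 groups gave 814 genes after TAC (477 higher, 337 lower), a fit with fewer samples. For the interaction, no filter on low values gave 16 genes, median-ratio scaling 199, and leaving out wild-type TAC replicate 5 and knockout TAC replicate 2 together 460; the cause was not tested. A block for replicate number gave 345 interaction genes (163 higher, 182 lower), but the numbers do not pair the libraries: residuals of same-numbered libraries correlated at -0.24 to 0.16 (22 pairs, mean -0.01), and 3 of 17 libraries were closest to their own number.

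With the term for library sets, 12 genes passed in sham, 243 after TAC and 17 for the interaction. Of sham values that had passed, those of Rpl37rt (0.09), Ndufb4b (0.19), Rps23rg1 (0.09) and the macrophage marker median (0.07) turned positive; the first 3 are among the 17 genes that define the sets. In all, 19 of 95 sham values of named genes turned, and 0 of these 19 passed with the term. Nppa went from -0.60 to 0.93, Postn from -0.36 to 1.32, Myh7 from -0.38 to 0.61, Acta1 from -0.54 to 0.75 and Myh6 from 0.08 to -0.10. After TAC Acta1 went from -0.16 to 0.88 and Hba-a2 from 0.38 to -0.01, and the interaction of Kcp from 0.01 to -0.01; these did not pass either way. By its construction the term carries the distance of wild-type TAC replicate 5 from the other wild-type TAC libraries, its weak TAC response included, into the sham values. Of the values of named genes beyond the 3 that had passed and turned, 94 lost the threshold. Another 57, uncalled in both fits, moved by more than their standard error. The remaining 431 kept their call and direction, however far they moved, or were uncalled in both fits and moved by no more than that. The other turned values are among those uncalled in both fits. The fits for genotype in sham and after TAC rest on wild-type TAC replicate 5. For TAC in wild type and the interaction the term instead takes that library out of the estimate, and the interaction count without it was 17 as well.

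Leaving out 1 library at a time gave 1981 to 2627 genes for TAC in wild type, 3720 to 4724 for TAC in knockout, 50 to 147 in sham, 663 to 1833 after TAC and 7 to 597 for the interaction; fewer samples lower such counts, and why some rose was not tested. The sham count of 151 was 86 and 78 without wild-type sham replicates 1 and 3, and 93, 50 and 73 without knockout sham replicates 1, 3 and 4. After TAC the count of 1350 was 870 without wild-type TAC replicate 4, and 663 and 857 without knockout TAC replicates 1 and 4. The interaction count was 23, 36, 10 and 33 without wild-type sham replicates 1 to 4, 43, 34 and 17 without wild-type TAC replicates 2, 4 and 5, 7, 43 and 58 without knockout sham replicates 1, 3 and 4, and 33, 597, 40, 30 and 171 without knockout TAC replicates 1 to 5. Of the values of named genes in these fits 484 lost the threshold, 61 gained it, and 25 that were uncalled in both fits moved by more than their standard error. The remaining 5250 kept their call and direction, or were uncalled in both fits and moved by no more than that, with their sign not considered.

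Of 66 list calls by camera 0 passed with an estimated correlation in place of the preset one. By fry 48 of them also passed in the same direction, and leaving out 1 library gave 61 to 70 calls. The correlation of the TAC responses across genes was 0.79, 0.77 with no filter and 0.76 to 0.81 without 1 library.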

Other observations

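Cell-type lists in the whole heart moved with TAC. Valve and cartilage-like markers, a list of tendon and cartilage matrix genes, rose in 2 of 5 genes in wild type (4 adjusted over the list alone; camera adjusted p = 0.012; adjusted p = 0.45 with an estimated correlation) and in 4 of 5 in knockout (4 adjusted over the list alone; camera adjusted p = 0.0047; adjusted p = 0.42 with an estimated correlation), with the cartilage matrix gene Comp at 2.86 ± 0.56, Fmod at 1.67 ± 0.41 and the tendon regulator Scx at 1.17 ± 0.14 in knockout. Fibroblast markers rose in 4 of 16 and fell in 2 in wild type (7 and 2 adjusted over the list alone; camera adjusted p = 0.012; adjusted p = 0.54 with an estimated correlation), and rose in 9 and fell in 2 in knockout (9 and 2 adjusted over the list alone; camera adjusted p = 0.033; adjusted p = 0.63 with an estimated correlation); Scara5, a marker of resting fibroblasts, fell by 0.55 on the log2 scale in wild type and by 1.04 in knockout. Adult cardiomyocyte genes fell in 10 of 23 and rose in 4 in wild type (11 and 4 adjusted over the list alone; camera adjusted p = 0.049; adjusted p = 0.50 with an estimated correlation), and fell in 13 and rose in 3 in knockout (13 and 3 adjusted over the list alone; camera adjusted p = 0.0011; adjusted p = 0.38 with an estimated correlation). In knockout, senescence-associated secretion genes rose in 8 of 17 and fell in 1 (8 and 1 adjusted over the list alone; camera adjusted p = 0.019; adjusted p = 0.45 with an estimated correlation), with Timp1, a protease inhibitor gene, at 2.48 ± 0.35. The wild-type call for adult cardiomyocyte genes was lost without wild-type sham replicate 1, 2 or 4 or wild-type TAC replicate 1, 3 or 4 (adjusted p = 0.079, 0.054, 0.051, 0.1, 0.068 and 0.06), and those for fibroblast markers without wild-type sham replicate 1 (0.054) in wild type and knockout sham replicate 4 (0.053) in knockout, which also ended that for senescence-associated secretion (0.077).

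Genes that differed between genotypes under both surgeries numbered 63, with 24 higher and 39 lower in knockout, where 5.02 and 3.54 would be shared by chance if the comparisons were independent, and 3 genes went in opposite directions; across all genes the changes correlated at r = 0.20 (Spearman rho = 0.04). Both comparisons carry the split between library sets, and 13 of the 39 lower genes are among the 17 that define it. Rab4a, Dynlt1b, Nnt and Wdfy1 were on the higher side and Plac9a and Plac9b on the lower side. Macrophage markers had a median of 0.23 after TAC (0 of 21 passed, 0 adjusted over the list alone; camera adjusted p = 0.048; adjusted p = 0.67 with an estimated correlation), a call not made without wild-type TAC replicate 2 or 5 or knockout TAC replicate 1, 2 or 4 (adjusted p = 0.092, 0.16, 0.08, 0.065 and 0.13). Ribosomal protein genes were higher in knockout after TAC in 9 of 36 (9 adjusted over the list alone; camera adjusted p = 0.00014; adjusted p = 0.51 with an estimated correlation), with Rpl3 at 0.56 ± 0.08. Camera also called the interaction of fetal and stress genes, TGF-beta signalling, G2/M genes, G1/S genes, immediate early genes, activated fibroblast and macrophage markers, senescence-associated secretion, apoptosis regulators and interferon response genes higher (adjusted p = 0.0019, 0.0047, 2.6e-05, 3.9e-05, 0.00054, 0.00063, 0.0011, 0.024, 0.024 and 0.012; adjusted p = 0.49, 0.45, 0.50, 0.51, 0.51, 0.50, 0.51, 0.45, 0.37 and 0.73 with an estimated correlation). Of these lists 6, 4, 5, 1, 0, 5, 0, 2, 2 and 0 genes were higher adjusted over the list alone. The tested G2/M and G1/S members may favour genes high in knockout TAC, because of the filter on low values. Adult cardiomyocyte and unfolded protein response genes were called lower (7 and 0 lower adjusted over the list alone; camera adjusted p = 0.0012 and 0.027; adjusted p = 0.38 and 0.55 with an estimated correlation). For immediate early genes, wild-type sham replicates 1 to 3 were high (means of 4.55, 4.07 and 4.57 on the log2 scale, against 3.23 in replicate 4). The interferon call was not made without wild-type sham replicate 3, whose list mean was 3.75 on the log2 scale against 2.3 to 2.68 in the other wild-type sham libraries, nor without knockout TAC replicate 2 (3.32 against 2.43 to 2.8) or knockout sham replicate 4 (adjusted p = 0.41, 0.11 and 0.05). That for senescence-associated secretion was not made without wild-type TAC replicate 5 or knockout sham replicate 4 (0.058 and 0.14), nor that for apoptosis regulators without knockout sham replicate 3 (0.058). The unfolded protein response was not called without wild-type sham replicate 3, wild-type TAC replicate 4, knockout sham replicate 4 or knockout TAC replicate 2 (0.063, 0.12, 0.34 and 0.1). In these 12 lists 1 gene, Tnni3 (-0.42 ± 0.10), passed over all tested genes, and it did not in 13 of 17 fits that left out 1 library.

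Lists called in none of the 5 contrasts by camera were BMP signalling, endothelial, neutrophil, blood cell, white fat, atrial, skeletal muscle, epicardial and mesothelial, nerve and glia markers, circadian clock and sex-linked genes. The lists for T and NK cells and for B cells had 0 and 2 tested members and were not tested. Kcp neighbours on chromosome 6 were called for TAC in knockout, where 6 of 21 rose and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.025; adjusted p = 0.37 with an estimated correlation), among them the filamin gene Flnc (1.34 ± 0.16).

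The tests below were planned. The real assignment of libraries to groups gave the most genes for 4 of the 5 counts here, and the interaction is described above. For TAC in wild type 1 of 100 splits, the real one, gave 2615 genes (highest other 1800). For TAC in knockout 1 of 56 gave 4633 (highest other 2084). In sham 1 of 35 gave 151 (highest other 9), and after TAC 1 of 100 gave 1350 (highest other 611). This argues against a chance assignment, but with as few as 35 or 56 splits it cannot exclude one. In sham the real split is also that of the library sets, so the test cannot tell genotype from set. Knockout sham replicate 2 lay between replicates 3 and 4 for 94.7% of the 76 genes that differ 2-fold between them (exact binomial 95% interval 87.1% to 98.5%; 78.9% for replicate 1, 68.1% to 87.5%), which is consistent with a mixture of their RNA or reads. Different sex of the mice is excluded, since 0 of 18 libraries had Xist above Ddx3y. Different DNA flanking Kcp on chromosome 6 stays open: 0 of 21 neighbours passed in sham (1-sided Fisher's exact p = 1; exact upper limit 16.1%, against 1.26% of all genes) and 2 of 21 after TAC (p = 0.7; upper limit 30.4%, against 11.3%).

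A different hour of tissue collection was tested with 16 clock genes. For TAC in knockout 11 passed, where 38.8% of all tested genes did. There 4 of 5 genes of opposite phase passed in opposite directions, so a different hour may contribute. For TAC in wild type 6 passed (21.9% of all genes did), with 1 of 5, which leaves it open. For genotype in sham 1 passed. As only 1.26% of all genes passed in sham, a low count there cannot argue against a different hour, which stays open. After TAC 3 passed (11.3% of all genes did), with 0 of 5 in opposite directions, which leaves it open.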
